A study of Ovis aries with 15 samples.

How the data were processed

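Total RNA of the kidney cortex of 15 fetal sheep was labelled with 1 dye and hybridised to Agilent ovine arrays, 1 array per fetus. The groups were normoxia with vehicle (3 arrays), normoxia with ketamine (4), hypoxia with vehicle (4) and hypoxia with ketamine (4). Per the file headers, the scanner intensity of each spot was background subtracted and spatially detrended within the array by Agilent Feature Extraction, on a linear scale and with no scaling between arrays. The deposited value table is on the log2 scale, and its columns have nearly equal quartiles and medians from 8.977 to 8.994, as after quantile normalization. The submitters name limma, and its version, the background correction and the filter behind the 11705 probes of that table are not given in the sources used here. After centring each probe, 12 of the 15 columns of the table tracked another array of their own group more closely than the array deposited with them (r from 0.909 to 0.976), so replicate numbers follow the scanner files. The number of arrays limits the precision.

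The analysis used the processed scanner intensity. Each array's log2 signal was taken relative to the array's 75th percentile, and spots not marked as outliers were averaged by probe. Of 15008 probes without controls, the 12925 called well above background by the scanner software on at least 3 of the 15 arrays were tested. The lowest signal called well above background was 6.97 to 18.7 over the arrays. The highest of these limits was that of hypoxia ketamine replicate 4, and on the other arrays it was at most 10.9. Where 1 of the 2 groups compared had no array well above background, each of its arrays was given at least its own limit, and the fold change is a lower bound. Genes for which only some arrays of a group were well above background are given as fitted changes.

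Gene names came from the array annotation, updated through a sheep RefSeq table for 1383 probes and through a hand-written table of older symbols for 143. That table was written after the array's names were seen and before any test was run. In all 1656 probes (11%) had a gene name, 1011 names in total, and 13352 probes had none.

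Linear models were fitted per probe in limma 3.58.1 (R 4.3.3) to all 15 arrays, with 1 mean per group and two-sided tests. Each probe had 1 moderated variance shared by the 4 groups (11 residual and 2.4 prior degrees of freedom). The 5 comparisons were hypoxia against normoxia in vehicle and in ketamine fetuses, ketamine against vehicle in hypoxic and in normoxic fetuses, and the hypoxia by ketamine interaction. Probes were counted at an unadjusted p of at most 0.05, the threshold per the labels, and at a Benjamini-Hochberg adjusted p of at most 0.05 within each comparison. In data tested on simulated changes, 200 of about 12900 probes were changed in 1 comparison. At a log2 change of 1, 60.5% were recovered after adjustment and 87.5% without, and at a log2 change of 2, 91% and 97%. Of the unchanged probes 4.89% and 4.83% passed the unadjusted threshold. The simulated probes were independent of each other and had the same spread in all groups. On the real arrays the hypoxic groups varied more than the normoxic ones (ratio of the median probe SD 1.39). These shares therefore do not give the power or the false call rate for the real arrays.

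In all, 34 gene lists were fixed before the data were examined, as were the groups, comparisons, thresholds, naming rule and most of the other settings tried. Lists with at least 5 measured genes (25) were tested with limma's camera at a preset correlation of 0.01, 1 probe per gene (the one with the highest mean signal), against 827 named genes, with adjustment over 125 tests. The lists too small to test were cytokine and chemokine receptors, B cells, MHC class II, acute-phase proteins, podocytes, nephron progenitors, erythroid genes, oxidative phosphorylation and sex-linked genes. Named genes were the probes past the adjusted threshold, the 8 largest increases and 8 largest decreases among genes past the unadjusted threshold whose group values did not overlap (a condition not set for the interaction), the 4 largest changes in each called list, and in the first 3 comparisons a fixed panel of inflammatory, hypoxic and kidney genes. The results of 1 gene under this rule are not reported here, and counts of named genes include it.

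The arrays lay on 2 slides, both holding arrays of every group, and list shifts and probe counts are also given within each slide and with slide as a block. Slide 2 held only replicate 3 of the normoxic vehicle group, so values against that group within slide 2 rest on this array. Replicate numbers were not taken as pairs, since arrays with the same number were only weakly correlated. These numbers followed the scanner files, and 12 of the 15 columns of the value table tracked another array. The weak correlation therefore cannot show that the fetuses were unpaired. The overlap between the response to hypoxia and the ketamine difference was set beside 100 simulated sets of unchanged groups. A first simulation gave degenerate values, and after its output was seen it was replaced by random mixes of each group's deviations from its mean. For the correlation between the hypoxia responses all 70 regroupings were used in place of the 100 draws planned, since no more exist.

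The other settings were normexp background correction (offset 50), quantile normalization, no filter, a filter on all 15 arrays, slide or replicate number as a block, the deposited value table, array weights, only the compared groups, camera with an estimated correlation, fry, the mean over a gene's probes, a threshold of 0.01 and leaving out each array. After the data were seen, 2 more were added, without the 2 arrays that stood apart on the first principal component and without the 3 arrays with placental lactogen well above background.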

Results

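Gene expression was measured in the kidney cortex of 15 chronically catheterised fetal sheep at about 125 d of gestation. Each mother was ventilated so that the fetus underwent 30 min of hypoxia or of normoxia, and the fetus received saline vehicle or ketamine (3 mg/kg, an anaesthetic that blocks NMDA-type glutamate receptors) 10 min beforehand. Cortex was collected 24 h after the exposure began. There were 3 normoxic vehicle, 4 normoxic ketamine, 4 hypoxic vehicle and 4 hypoxic ketamine fetuses, with 1 array per fetus. The arrays were 1-colour Agilent ovine arrays with 15008 probes, of which 12925 were tested, and only 11% of the probes carried a gene name. The 75th percentile of the signal lay between 1064 and 1425 over the arrays, and 75.7% to 85.2% of the probes were well above background. The lowest share was that of hypoxia ketamine replicate 4, and every other array had at least 81.0%. The number of arrays limits the precision. Below, "rose" and "fell" mean an unadjusted p of at most 0.05 in limma, the threshold the study states, and a gene list is called at an adjusted p of at most 0.05 in limma's camera test. Where a call is said to be lost without an array or under another setting, the value in parentheses is the log2 change obtained then, or the adjusted p for a list. Not every list call lost under another setting is named, and counts are given in the part on processing. Each SE, given after ±, comes from 1 variance per probe shared by all 4 groups. The hypoxic groups varied more than the normoxic ones, so it can be too small for comparisons between hypoxic groups.

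The first question was what hypoxia alone did to the cortex. In vehicle fetuses, several cytokines and chemokines were higher after hypoxia than after normoxia. TNF, a cytokine of activated macrophages, rose 16.5-fold (log2 change 4.05 ± 0.67, SE, 4 against 3 fetuses). IL1B rose 11.8-fold (3.56 ± 0.78) and CXCL8, a neutrophil attractant, rose 23.6-fold (4.56 ± 1.24). IL6 was well above background on 2 of 4 hypoxic and 0 of 3 normoxic arrays and was at least 26.9-fold higher. PTX3, a pattern recognition protein induced by cytokines, rose 32.8-fold (5.04 ± 1.41), and SELP, the P-selectin of activated endothelium and platelets, rose 28.8-fold (4.85 ± 1.15). ICAM1, an adhesion molecule for leukocytes, rose 6.48-fold (2.70 ± 0.84), and IL1RN, the antagonist of the interleukin 1 receptor, rose 12.8-fold (3.68 ± 0.97).

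As a group, 7 of the 11 measured cytokines and chemokines rose and 0 fell, 6 of them when adjusted over the list alone and 0 over all probes, and the list was called (adjusted p = 1.0e-04). Its mean shift of 2.56 was 2.66 with slide as a block, 2.97 within slide 1 and 2.23 within slide 2. The list score was 3.70 in hypoxia vehicle replicate 4, between -0.02 and 0.70 in the other 3 hypoxic and between -1.1 and -0.62 in the normoxic vehicle fetuses. Of 12 toll-like receptor and NF-kB genes, 7 rose and 0 fell (7 adjusted over the list alone, 0 over all probes; adjusted p = 0.00303). They included NFKBIA, the inhibitor that NF-kB itself induces (5.85-fold, 2.55 ± 0.54), TLR2 (4.11-fold, 2.04 ± 0.62) and CD14 (1.93-fold, 0.95 ± 0.31), with a mean shift of 0.80 (0.83 blocked, 1.07 and 0.46 within the slides). Both calls were lost with an estimated correlation (adjusted p = 0.676 for each). TLR4, the receptor for bacterial lipopolysaccharide, rose 2.22-fold, but not without normoxia vehicle replicate 1 (0.97), replicate 2 (1.1) or hypoxia vehicle replicate 4 (0.68).

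Of 8 monocyte and macrophage markers, 4 rose and 0 fell (4 adjusted over the list alone, 0 over all probes; adjusted p = 0.0125). FCGR1A rose 5.46-fold (2.45 ± 0.54), FCGR2B 4.71-fold (2.24 ± 0.70), CD86 3.14-fold (1.65 ± 0.42) and FCER1G 2.05-fold (1.04 ± 0.39). The first 3 are an Fc receptor of high affinity, an inhibitory Fc receptor and a T cell costimulator. The mean shift was 1.14 (1.14 blocked, 1.17 and 0.97 within the slides), and the call was lost with an estimated correlation (adjusted p = 0.676). It was also lost without hypoxia vehicle replicate 2 (0.0598) or replicate 3 (0.0743), and FCER1G did not rise without normoxia vehicle replicate 3 (1.0) or hypoxia vehicle replicate 3 (0.69).

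Among 11 targets of the hypoxia-inducible factors, 4 rose and 0 fell (4 adjusted over the list alone, 0 over all probes; adjusted p = 0.0166). These were the glucose transporters SLC2A3 (2.0 ± 0.47) and SLC2A1 (1.92-fold, 0.94 ± 0.27), lactate dehydrogenase LDHA (2.39-fold, 1.26 ± 0.36) and aldolase ALDOA (1.40-fold, 0.48 ± 0.17). The angiogenic factor VEGFA, also a target, differed by 0.04 ± 0.30, which did not pass. Of 8 immediate early genes, transcribed within minutes of a stimulus, 4 rose and 0 fell (1 adjusted over the list alone, 0 over all probes; adjusted p = 0.00303), led by JUNB (6.94-fold, 2.80 ± 0.74). The mean shifts were 0.58 for the hypoxia-inducible targets (0.57 blocked, 0.40 and 0.75 within the slides) and 1.34 for the immediate early genes (1.33 blocked, 1.30 and 1.41). Both calls were lost with an estimated correlation (adjusted p = 0.676 for each), and that of the hypoxia-inducible targets also without hypoxia vehicle replicate 1 (0.074). ALDOA did not rise without normoxia vehicle replicate 1 (0.39). Of the other immediate early genes, MYC (2.84-fold) did not rise without normoxia vehicle replicates 2 or 3 or hypoxia vehicle replicates 1 or 4 (1.04 to 1.49). ZFP36 (2.62-fold) did not without normoxia vehicle replicate 1 or hypoxia vehicle replicates 1 or 4 (0.96 to 1.30), and JUN (1.38-fold) did not without any 1 of the normoxic vehicle arrays or hypoxia vehicle replicates 1 or 4 (0.34 to 0.50), nor with quantile scaling (0.38).

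Of 12 extracellular matrix and fibroblast genes, 5 fell and 0 rose (3 adjusted over the list alone, 0 over all probes; adjusted p = 0.0443, and 0.676 with an estimated correlation). They included the collagenase MMP2 (log2 change -0.67 ± 0.21) and the collagen chains COL3A1 (-0.57 ± 0.14) and COL1A2 (-0.45 ± 0.17; not called without normoxia vehicle replicate 2, -0.39). The mean shift was -0.20 (-0.20 blocked, -0.19 and -0.16 within the slides). The call ended with slide as a block (0.0576), with quantile scaling (0.0673) and without normoxia vehicle replicate 1 (0.151), normoxia ketamine replicate 4 (0.0554), hypoxia vehicle replicates 2 (0.112) or 3 (0.148), or hypoxia ketamine replicate 4 (0.0527). IGF1, insulin-like growth factor 1, fell by 1.15 ± 0.21, SNAI2, a repressor of epithelial genes, by 1.48 ± 0.31, and AGTR1, the angiotensin II receptor, by 1.09 ± 0.31. The adaptor LAT2 (-1.85 ± 0.56), the mitochondrial SIRT4 (-1.29 ± 0.42, and -0.60 without normoxia vehicle replicate 3), the integrin ITGA4 (-1.22 ± 0.44), the homeobox gene BARX2 (-1.2 ± 0.34) and the glutamate receptor subunit GRIA4 (-0.98 ± 0.28) also fell. TGFBR1, a TGF-beta receptor, fell by 0.47 ± 0.21, but not without any 1 of normoxia vehicle replicates 1 and 2, the 4 normoxic ketamine arrays, hypoxia vehicle replicates 2 and 3 and hypoxia ketamine replicates 1 and 3 (-0.47 to -0.30). With normexp background correction LAT2 (-0.70), SIRT4 (-0.57), ITGA4 (-0.62), BARX2 (-0.51), GRIA4 (-0.32) and TGFBR1 (-0.28) no longer passed.

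The metabolic genes IGFBP1, which binds insulin-like growth factors, and CYP24, which inactivates vitamin D, rose 15.4-fold (3.95 ± 1.62) and 12.2-fold (3.60 ± 1.05). IGFBP1 was not called without normoxia vehicle replicates 2 or 3 or hypoxia vehicle replicates 1 or 3 (2.77 to 3.93), nor with normexp (2.45). Of 7 tubular injury markers, only IL18 rose (0.87 ± 0.21; 2 of its 3 probes went the same way, and with normexp it did not pass at 0.38) and 0 fell (1 adjusted over the list alone, 0 over all probes). That list had a mean shift of 0.50 (0.50 blocked, 0.55 and 0.45 within the slides) and an adjusted p of 0.0393 (0.676 with an estimated correlation), which the slide block (0.0698), quantile scaling (0.13) and normexp (0.201) ended. It also ended without normoxia vehicle replicate 1 (0.0687), hypoxia vehicle replicates 1 (0.0827), 3 (0.0554) or 4 (0.0776), or hypoxia ketamine replicates 2 (0.0633) or 4 (0.0518). The other 18 tested lists were not called.

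Over the whole array, 747 probes rose and 1340 fell, 2087 against the 646 that chance gives at this threshold. After Benjamini-Hochberg adjustment in limma, 2 unnamed probes remained. A_70_P048566 was 4.47-fold higher (2.16 ± 0.29, adjusted p = 0.0271, all 4 hypoxic arrays above all 3 normoxic ones). A_70_P000721 was at least 1.77-fold lower and not well above background in the hypoxic vehicle fetuses (adjusted p = 0.0126), and with normexp it did not pass the unadjusted threshold (-0.43). With slide as a block 2161 probes passed, within slide 1 1204 and within slide 2 664. With only these 2 groups in the model TLR4 (1.15), MYC (1.51), ZFP36 (1.39), JUN (0.47) and TGFBR1 (-0.47) did not pass. With the replicate block TLR4 (0.998), JUN (0.44) and TGFBR1 (-0.46) did not, and from the deposited values JUN (0.36) and TGFBR1 (-0.25). Without the 2 arrays that stood apart ITGA4 (-1.025), MYC (1.14), ZFP36 (0.96) and JUN (0.34) did not, and without the 3 with placental lactogen JUN (0.47) and TGFBR1 (-0.47). Without normoxia vehicle replicate 2, 1304 passed, and without hypoxia vehicle replicate 3, 4 of the 7 lists were called.

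**Figure D1:**
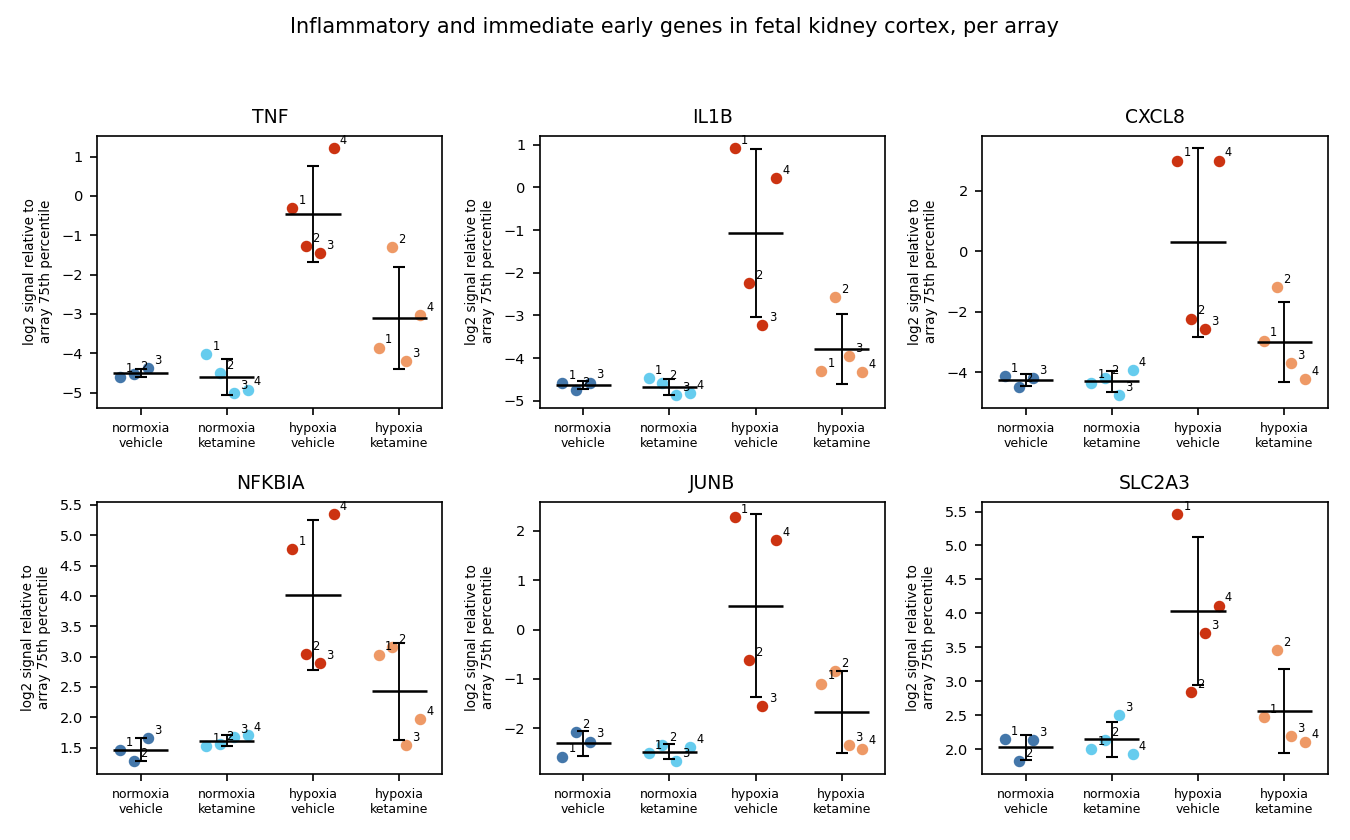
Log2 signal relative to the array's 75th percentile for TNF, IL1B, CXCL8, NFKBIA, JUNB and SLC2A3 on each of the 15 arrays by group, with replicate numbers, a horizontal line at each group mean and bars of 1 SD. TNF lies between -1.45 and 1.22 in the hypoxic vehicle fetuses and between -4.19 and -1.30 in the hypoxic ketamine fetuses.

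The same comparison in ketamine fetuses asked whether hypoxia changed the cortex when the drug had been given. Markers of monocytes and macrophages were higher after hypoxia here as well. Of 8 markers, 4 rose and 0 fell (4 adjusted over the list alone, 0 over all probes; adjusted p = 1.06e-04, and 0.676 with an estimated correlation). CD86 rose 2.60-fold (1.38 ± 0.39, 4 against 4 fetuses), FCER1G 2.25-fold (1.17 ± 0.36) and FCGR1A 2.76-fold (1.46 ± 0.50). FCGR2B rose 3.21-fold, but not without normoxia ketamine replicates 1 (1.48) or 3 (1.57) or hypoxia ketamine replicate 2 (1.1). Without the 3 arrays with placental lactogen, hypoxia ketamine replicate 2 among them, none of the 4 was called. CD86 was then 0.81, FCER1G 0.81, FCGR1A 0.87 and FCGR2B 0.94. The mean shift of the markers was 1.11 (1.11 blocked, 1.59 and 0.63 within the slides).

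Of the 11 cytokines and chemokines 2 rose and 0 fell (0 adjusted over the list alone, 0 over all probes in limma; adjusted p = 0.0122, and 0.676 with an estimated correlation). CXCL10, an interferon-induced chemokine, rose 8.87-fold (3.15 ± 1.42) and TNF 2.86-fold (1.52 ± 0.62). TNF was not called without normoxia ketamine replicates 3 or 4 or hypoxia ketamine replicates 2 or 4 (0.92 to 1.5). CXCL10 was not called without normoxia vehicle replicates 1 or 2, normoxia ketamine replicates 2 to 4, hypoxia vehicle replicate 2 or hypoxia ketamine replicates 2 to 4 (2.15 to 3.41), nor with normexp (2.81). IL1B differed by 0.90 ± 0.72, CXCL8 by 1.29 ± 1.15 and ICAM1 by 1.01 ± 0.78, none of which passed. IL6 was well above background on 3 of 4 hypoxic and 0 of 4 normoxic arrays and at least 1.87-fold higher (adjusted p = 0.83). The list's mean shift was 1.15 (1.15 blocked, 1.37 and 0.92 within the slides), and normexp ended its call (0.119).

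In the other immune groups, 1 of 5 neutrophil markers rose and 0 fell (0 adjusted over the list alone, 0 over all probes in limma; adjusted p = 0.019). This was CATHL3, a cathelicidin (9.03-fold, 3.18 ± 1.25), which was not called without normoxia ketamine replicate 2 (2.78) or hypoxia ketamine replicates 2 (2.31) or 4 (2.79). Of 5 interferon-stimulated genes 0 passed singly at the unadjusted threshold in limma, yet all 5 lay higher (median 2.19, adjusted p = 0.0125). Of 12 toll-like receptor and NF-kB genes 1 rose, TLR3 (1.67-fold, 0.74 ± 0.26), and 0 fell (0 adjusted over the list alone, 0 over all probes; adjusted p = 0.0407). TLR2 differed by 0.40 ± 0.57, CD14 by 0.28 ± 0.29 and TLR4 by -0.31 ± 0.43, and without hypoxia ketamine replicate 2 the first 2 turned to -0.20 and -0.02. All 3 list calls were lost with an estimated correlation (adjusted p = 0.676 for each). Without hypoxia ketamine replicate 2 the neutrophil (0.126), interferon (0.107) and toll-like receptor (0.296) calls ended. The neutrophil call also ended without normoxia ketamine replicate 1 (0.0658) or hypoxia ketamine replicate 4 (0.0687), and the toll-like receptor call without normoxia ketamine replicates 2 (0.0801), 3 (0.0681) or 4 (0.0687). Normexp ended the interferon call (0.0637). The mean shifts were 1.49 for neutrophil markers (1.49 blocked, 2.79 and 0.19 within the slides), 2.15 for interferon-stimulated genes (2.15, 3.13 and 1.18) and 0.30 for toll-like receptor genes (0.30, 0.40 and 0.20).

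Among single genes, the peptide transporter SLC15A1 rose 5.16-fold (2.37 ± 0.61), the lectin receptor CLEC6A 3.4-fold (1.77 ± 0.55, and 1.099 without hypoxia ketamine replicate 2) and the growth factor FLT3LG 1.83-fold (0.87 ± 0.24). RTP4 (4.32-fold) and the adenosine receptor ADORA3 (2.01-fold) rose, but RTP4 did not without any 1 of the normoxic ketamine arrays or hypoxia ketamine replicate 2 (1.33 to 2.21), and ADORA3 did not without normoxia ketamine replicates 2 or 3 or hypoxia ketamine replicate 2 (0.76 to 0.97). ITGA4 fell by 1.70 ± 0.41, NTN4, a basement membrane netrin, by 0.98 ± 0.19, IL13RA1 by 0.68 ± 0.16 and IGF1 by 0.68 ± 0.19. CYP4F21 (-1.44 ± 0.50, and -0.93 without normoxia ketamine replicate 2), CLMP (-0.74 ± 0.25), the bicarbonate transporter SLC4A4 (-0.61 ± 0.16) and the circadian regulator CLOCK (-0.59 ± 0.14) also fell. With normexp CYP4F21 (-0.36), CLMP (-0.16), SLC4A4 (-0.05), ITGA4 (-0.59) and IGF1 (-0.24) did not pass, and CLOCK turned to 0.08. SLC2A1 (0.46 ± 0.25) and VEGFA (-0.22 ± 0.28) did not pass.

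In all, 479 probes rose and 642 fell, and 0 passed after adjustment in limma (1121 unadjusted). With slide as a block 1158 passed, within slide 1 606 and within slide 2 820. The share of higher calls was 42.7% and became 54.8% without the arrays with placental lactogen and 63.2% with normexp, which moved the median of all probes from -0.02 to 0.09. Placental lactogen was well above background in normoxia ketamine replicates 1 and 2 and hypoxia ketamine replicate 2; without these 3 arrays, chosen after the data were seen, 819 probes passed and 1 list was called in place of 5. CD86 (0.81), FCER1G (0.81), FCGR1A (0.87), FCGR2B (0.94), CLEC6A (0.96), RTP4 (1.45), ADORA3 (0.77), CATHL3 (1.58), CXCL10 (2.81), TNF (1.27), TLR3 (0.63) and CLMP (-0.56) were then not called, and TLR2 was -0.32. From the deposited values CXCL10 (2.89) was not called. Without the 2 arrays that stood apart CATHL3 (2.31), ADORA3 (0.76) and FCGR2B (1.104) were not. Without hypoxia ketamine replicate 2 alone, 3 lists were called.

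The 2 hypoxia comparisons share no arrays. Across probes their log2 changes correlated at r = 0.606, with probes not independent of each other, and 86.7% of the probes called in vehicle fetuses went the same way in ketamine fetuses. Regrouping the 8 ketamine arrays in all 70 ways gave as high a correlation 3 times (exact permutation p = 0.0429, one-sided). Among the calls, 164 probes rose in both where independent lists would share 27.7, 286 fell in both where 66.6 would be shared, and 7 were called in opposite directions. Without hypoxia ketamine replicate 2 the correlation was 0.393.

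The main question of the study, as its title gives it, was whether ketamine lowered the inflammatory response to hypoxia. Immediate early genes and cytokines were lower in hypoxic ketamine than in hypoxic vehicle fetuses. Of 8 immediate early genes, 7 fell and 0 rose (4 adjusted over the list alone, 0 over all probes; adjusted p = 1.55e-05, and 0.676 with an estimated correlation). JUNB fell by 2.16 ± 0.69 (SE from the model of all 4 groups, 4 against 4 fetuses), and the matricellular gene CCN1 by 1.37 ± 0.57. FOS fell by 2.04 ± 0.93 and ZFP36, which destabilises cytokine messengers, by 1.27 ± 0.48. The list score was 1.76 and 2.28 in hypoxia vehicle replicates 1 and 4, -0.22 and -0.19 in replicates 2 and 3, and between -0.58 and -0.01 in the 4 hypoxic ketamine fetuses. FOS was not called with slide as a block (-2.04), nor without either of hypoxia vehicle replicates 1 and 4 (-1.29 and -1.44), normoxia vehicle replicates 1 or 3, normoxia ketamine replicates 1 to 3 or hypoxia ketamine replicates 1, 3 or 4 (-2.17 to -1.59). CCN1 was not called without hypoxia vehicle replicates 1 or 4 or hypoxia ketamine replicates 2 or 4 (-1.34 to -0.71), and ZFP36 was not without hypoxia vehicle replicates 1 or 4 (-0.91 to -0.84). The mean shift was -1.28 (-1.28 blocked, -1.30 and -1.25 within the slides).

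Of the 11 cytokines and chemokines, 4 fell and 0 rose (3 adjusted over the list alone, 0 over all probes; adjusted p = 0.00303, and 0.676 with an estimated correlation). CXCL8 fell by 3.31 ± 1.15, and IL1B (-2.71 ± 0.72), TNF (-2.65 ± 0.62) and IL1A (-2.40 ± 0.90) fell as well, the last not without hypoxia vehicle replicates 1 (-1.84) or 4 (-1.62). IL6 was well above background on 2 of 4 vehicle and 3 of 4 ketamine arrays. Its fitted change was -4.21 within slide 1 and -3.53 within slide 2, and it was not called. The list score was 3.70 in hypoxia vehicle replicate 4 and 0.59, 0.70 and -0.02 in replicates 1 to 3, and in the ketamine fetuses 1.501 in replicate 2 and -0.23 to -0.11 in the others, so 1 fetus carried much of the difference. The mean shift was -1.49 (-1.49 blocked, -1.61 and -1.36 within the slides). Of the 12 toll-like receptor and NF-kB genes, 4 fell and 0 rose (0 adjusted over the list alone, 0 over all probes in limma; adjusted p = 0.0168, and 0.676 with an estimated correlation). TLR2 fell by 1.66 ± 0.57, NFKBIA by 1.59 ± 0.50 and the adaptor MYD88 by 0.47 ± 0.17. TLR4 fell by 0.95 ± 0.43, but not with slide as a block (-0.95), quantile scaling (-0.89) or normexp (-0.53), nor without any 1 array except normoxia vehicle replicate 3, hypoxia vehicle replicates 2 and 3 and hypoxia ketamine replicate 2 (-1.03 to -0.48). TLR2 (-0.77) and MYD88 (-0.09) did not pass with normexp. The toll-like receptor list shifted by -0.51 (-0.51 blocked, -0.53 and -0.48 within the slides), and its call ended with normexp (0.125) and without hypoxia vehicle replicate 4 (0.272) or hypoxia ketamine replicates 3 (0.055) or 4 (0.0595). CD14 (-0.36 ± 0.29) and ICAM1 (-1.45 ± 0.78) did not pass.

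Of 11 hypoxia-inducible targets, 4 fell and 0 rose (0 adjusted over the list alone, 0 over all probes in limma; adjusted p = 1.0e-04, and 0.676 with an estimated correlation), and all 11 lay lower. SLC2A3 fell by 1.47 ± 0.44, VEGFA by 0.69 ± 0.28, SLC2A1 by 0.61 ± 0.25 and hexokinase HK1 by 0.57 ± 0.20. For VEGFA this was not a smaller rise, since hypoxia had not raised it in vehicle fetuses (0.04). It also lay lower with ketamine in normoxic fetuses (-0.43), and its interaction was -0.26, neither of them called. VEGFA was not called without hypoxia vehicle replicates 1 or 3 or hypoxia ketamine replicate 4 (-0.62 to -0.42), SLC2A1 was not without hypoxia vehicle replicates 1 or 3 or hypoxia ketamine replicate 3 (-0.50 to -0.40), and HK1 was not without hypoxia vehicle replicate 1 (-0.39). Of 8 heat shock and unfolded protein response genes, the chaperone HSPA1A fell (-0.68 ± 0.22) and 0 rose (0 adjusted over the list alone, 0 over all probes; adjusted p = 0.016, and 0.676 with an estimated correlation). That call ended without hypoxia vehicle replicates 1 (0.074) or 4 (0.193) or hypoxia ketamine replicate 2 (0.108). The mean shifts were -0.63 for the hypoxia-inducible targets (-0.63 blocked, -0.33 and -0.92 within the slides) and -0.37 for the heat shock genes (-0.37, -0.37 and -0.36).

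Outside the lists, IL13RA1, a receptor chain for interleukin 13, fell by 0.87 ± 0.16, the signalling adaptor TRAF3 by 0.61 ± 0.19 (-0.40 without hypoxia vehicle replicate 4), the enzyme of pyrimidine synthesis UMPS by 0.46 ± 0.13 and the transcription factor CREB1 by 0.42 ± 0.13. TRAF3 (-0.22), UMPS (-0.12) and CREB1 (-0.16) did not pass with normexp. BCL2, an inhibitor of apoptosis, fell by 0.52 ± 0.20, but not without hypoxia vehicle replicates 3 or 4 or hypoxia ketamine replicate 4 (-0.47 to -0.37). The liver type glycogen phosphorylase PYGL rose 1.49-fold (0.58 ± 0.23), but not without hypoxia vehicle replicates 2 or 4 or hypoxia ketamine replicate 2 (0.40 to 0.52).

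Altogether 334 probes rose and 451 fell, 785 against the 646 of chance, and 0 passed after adjustment in limma. With only the 2 hypoxic groups in the model, 431 passed unadjusted, fewer than chance gives. With slide as a block 772 passed, within slide 1 276 and within slide 2 875. The share of higher calls went from 42.5% to 50.4% with quantile scaling, to 51.8% in the deposited value table and to 53.9% with normexp, and with normexp the median of all probes from 0.02 to 0.12. The count was 1552 without hypoxia vehicle replicate 2, 1606 without hypoxia ketamine replicate 2 and 487 without hypoxia ketamine replicate 4. It was 1460 without the 3 arrays with placental lactogen and 1248 without the 2 arrays that stood apart, hypoxia vehicle replicate 4 and hypoxia ketamine replicate 2. With only the 2 groups in the model CXCL8 (-3.31), IL1A (-2.40), TLR4 (-0.95), MYD88 (-0.47), VEGFA (-0.69), SLC2A1 (-0.61), HK1 (-0.57), FOS (-2.04), CCN1 (-1.37) and ZFP36 (-1.27) were not called. The replicate block ended the calls of TLR4 (-0.95) and FOS (-2.04), array weights that of PYGL (0.42), and the deposited values those of CREB1 (-0.27), TLR4 (-0.77) and MYD88 (-0.25). Leaving out the 2 arrays, PYGL (0.35), BCL2 (-0.41), IL1A (-1.61), HSPA1A (-0.51), FOS (-1.79), CCN1 (-0.68) and ZFP36 (-0.91) were not called, and without the 3 arrays IL1A (-2.39), VEGFA (-0.69), FOS (-2.39) and CCN1 (-1.34).

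Of the 2087 probes changed by hypoxia in vehicle fetuses, 331 (15.9%) changed the other way between hypoxic ketamine and hypoxic vehicle fetuses, and 83.9% lay in the opposite direction (r = -0.662 across probes, covariance -0.129). Both comparisons use the hypoxic vehicle arrays, so such opposition arises by chance. Groups simulated without any effect gave a mean share of 35.9%, a correlation of -0.601 and a covariance of -0.0873. They ranged from 0 to 93.8%, from -0.967 to -0.105 and from -0.417 to -0.00402, and the observed values lay within these ranges. The simulated sets called 0 to 5703 probes after hypoxia, and nearly any share would lie within so wide a range. The simulation therefore cannot decide whether ketamine reversed the hypoxia change. With the 4 hypoxic vehicle arrays split between the comparisons, the share was 7.33% (1.95% to 10.8% over 6 splits), 53.9% lay in the opposite direction, and the correlation was -0.179. The share was 34.3% without hypoxia vehicle replicate 2, 26.0% without hypoxia vehicle replicate 3, 31.9% without hypoxia ketamine replicate 2, 7.99% without hypoxia ketamine replicate 3 and 10.0% without hypoxia ketamine replicate 4.

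**Figure D2:**
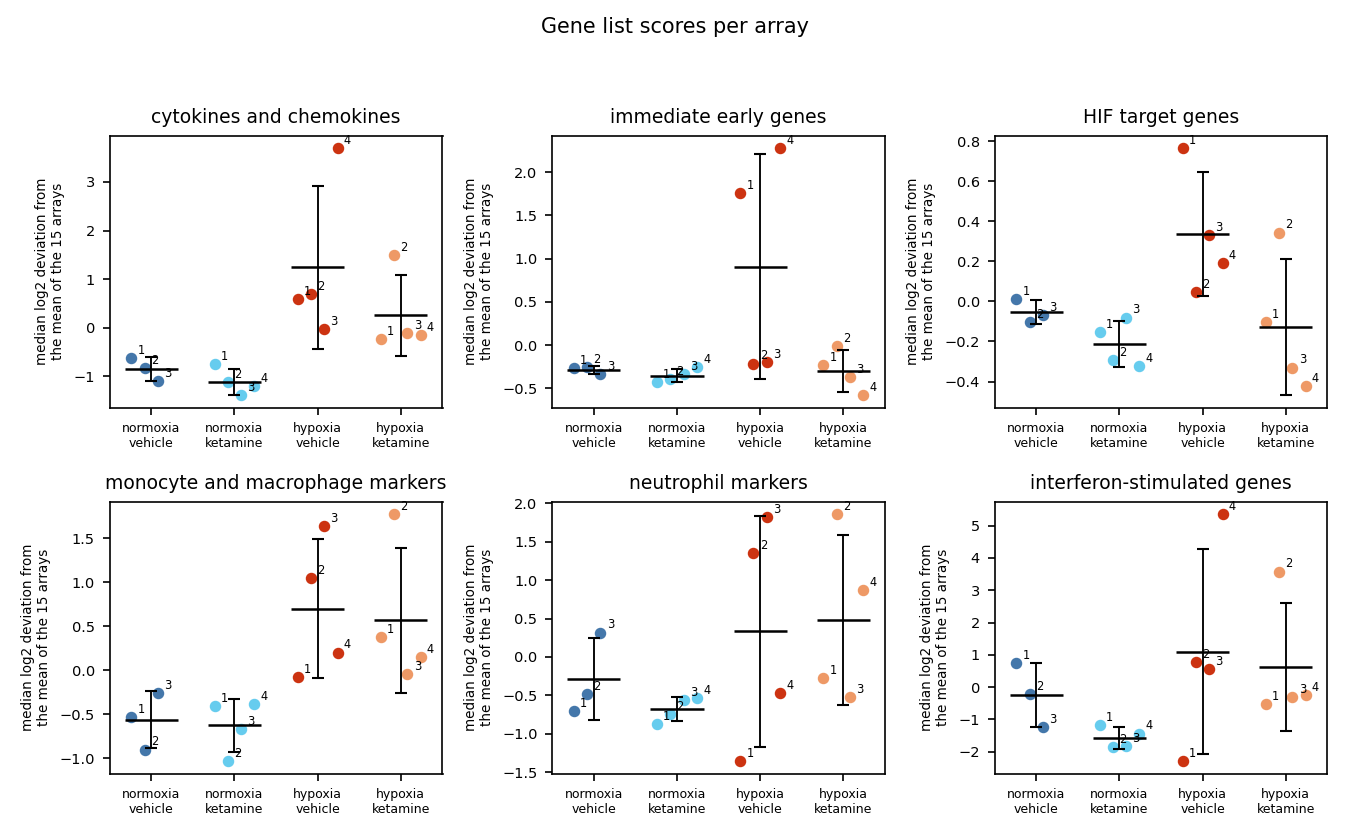
Scores of 6 gene lists on each array, as the median over a list's members of the log2 deviation from the mean of the 15 arrays, with replicate numbers, a horizontal line at each group mean and bars of 1 SD. Immediate early genes are high in hypoxia vehicle replicates 1 (1.76) and 4 (2.28), and interferon-stimulated genes in hypoxia vehicle replicate 4 (5.36) and hypoxia ketamine replicate 2 (3.58).

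In normoxic fetuses, ketamine against vehicle asked what the drug did on its own, and few probes passed in the model of all 4 groups. That model gave each probe 1 variance for all groups. The median probe SD was 0.176 in normoxic vehicle and 0.206 in normoxic ketamine fetuses, against 0.289 and 0.238 in the hypoxic ones. PAG10, a pregnancy-associated glycoprotein known from the placenta, rose 4.33-fold (2.11 ± 0.79, 4 against 3 fetuses). It was not called with normexp (0.65) or without normoxia vehicle replicate 3 (1.98) or normoxia ketamine replicates 1 (1.65) or 2 (1.46). CHRD, an antagonist of bone morphogenetic proteins, fell by 0.90 ± 0.24 and the growth factor PDGFB by 0.47 ± 0.14, neither of them with normexp (-0.42 and -0.34). SIRT4 fell by 1.17 ± 0.42, but not with normexp (-0.56) or without normoxia vehicle replicate 3 (-0.48). The cell cycle inhibitor CDKN1B fell by 0.60 ± 0.23 and the carnitine carrier SLC25A20 rose 1.86-fold (0.90 ± 0.29), neither without normoxia vehicle replicate 2 (-0.46 and 0.68), and CDKN1B did not with normexp (-0.50).

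Of 6 cell cycle genes, 0 passed singly in limma at the unadjusted threshold and all 6 lay higher (median 0.30, 0 adjusted over the list alone; adjusted p = 0.0125, and 0.676 with an estimated correlation). The call ended without normoxia vehicle replicates 1 (0.0752) or 3 (0.151). The mean shift was 0.29 (0.31 blocked, 0.33 and 0.29 within the slides). The remaining named genes changed little, SHMT1 (0.50), GATD3 (0.33), PDIA5 (0.33), COX15 (0.31) and PRKAR1A (0.28) rising and TFAP2A (-0.44) and CAPN1 (-0.43) falling. CFTR, a chloride channel, was well above background on 2 of 4 ketamine and 0 of 3 vehicle arrays and at least 1.03-fold higher, and with normexp it turned to -0.13. These 8 calls were each lost without at least 1 of the 7 normoxic arrays, for example SHMT1 without normoxia vehicle replicate 3 (0.40), GATD3, PDIA5 and COX15 without replicate 1 (0.30, 0.29 and 0.25), CFTR without replicate 1 (0.69), TFAP2A without replicate 3 (-0.38) and PRKAR1A and CAPN1 without replicate 2 (0.17 and -0.37). With normexp SHMT1 (0.28), GATD3 (0.34), COX15 (0.19) and PRKAR1A (0.30) did not pass.

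In this comparison 123 probes rose and 227 fell, 350 where chance gives 646, and 0 passed after adjustment in limma. With only the 2 normoxic groups in the model, 671 passed unadjusted and 1 adjusted. With slide as a block 406 passed, within slide 1 250 and within slide 2 275. The share of higher calls was 35.1%, and 51.1% with quantile scaling, 52.2% with normexp, 46.8% in the deposited value table, 55.7% with the replicate block, 55.3% without normoxia ketamine replicate 4 and 20.1% without the 3 arrays with placental lactogen. Without normoxia vehicle replicate 2 there were 211 and without normoxia vehicle replicate 3 540. Without the 2 arrays that stood apart there were 556. Without the 3 arrays with placental lactogen PAG10 (0.45), CFTR (0.62), SHMT1 (0.35), GATD3 (0.26), COX15 (0.26), PRKAR1A (0.19), CDKN1B (-0.50), TFAP2A (-0.37) and CAPN1 (-0.40) were not called. With only the 2 groups in the model PAG10 (2.11), PDIA5 (0.33) and PRKAR1A (0.28) were not, with the replicate block PRKAR1A (0.28) and TFAP2A (-0.42), with quantile scaling PRKAR1A (0.22), and from the deposited values PRKAR1A (0.19), SIRT4 (-0.46) and PDGFB (-0.27).

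**Figure D3:**
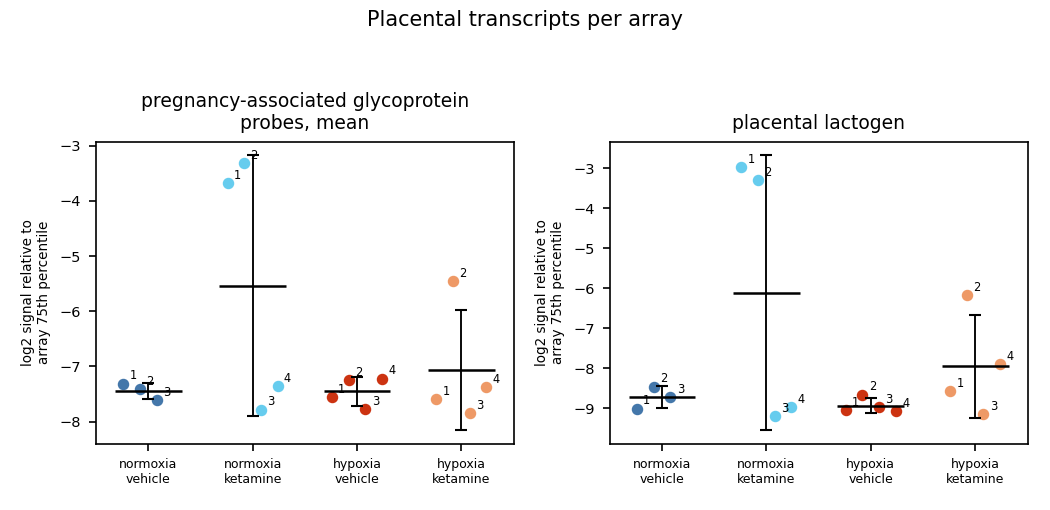
Mean log2 signal, relative to the array's 75th percentile, of the 9 tested pregnancy-associated glycoprotein probes (left) and of the placental lactogen probe (right) on each array, with replicate numbers, a horizontal line at each group mean and bars of 1 SD. Normoxia ketamine replicates 1 (-3.68) and 2 (-3.32) and hypoxia ketamine replicate 2 (-5.46) lie above the other arrays on the left, which end at -7.22.

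Whether the response to hypoxia differed with ketamine was tested as the interaction, in which a negative value means a smaller or more negative response under ketamine. The toll-like receptor (adjusted p = 0.142) and monocyte (0.917) lists were not called. TNF had an interaction of -2.53 ± 0.91, IL1B of -2.66 ± 1.06 and SLC2A3 of -1.59 ± 0.64. Of the 11 cytokines and chemokines 2 fell and 0 rose (0 adjusted over the list alone, 0 over all probes in limma; adjusted p = 0.0168), and of the 11 hypoxia-inducible targets 1 fell and 0 rose (0 adjusted over the list alone; adjusted p = 0.0223). Of 8 immediate early genes (adjusted p = 0.00303) and 8 heat shock genes (adjusted p = 0.0406) 0 passed singly at the unadjusted threshold, and all 8 of each lay lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.676 for each). IL1B was not called with normexp (-1.71) or without hypoxia vehicle replicate 4 (-2.23), and SLC2A3 was not without normoxia vehicle replicate 2, normoxia ketamine replicate 3 or hypoxia ketamine replicates 3 or 4 (-1.48 to -1.44).

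The mean interaction was -1.41 for cytokines (-1.51 blocked, -1.60 and -1.31 within the slides), -0.55 for hypoxia-inducible targets (-0.54, -0.25 and -0.84), -1.12 for immediate early genes (-1.11, -1.002 and -1.27) and -0.43 for heat shock genes (-0.42, -0.43 and -0.38). The cytokine call ended without normoxia vehicle replicate 3 (0.0622), normoxia ketamine replicate 4 (0.0687) or hypoxia vehicle replicate 4 (0.181). The call of the hypoxia-inducible targets ended without normoxia vehicle replicate 3 (0.0809), normoxia ketamine replicate 3 (0.0565), hypoxia vehicle replicates 1 (0.103) or 3 (0.065) or hypoxia ketamine replicate 4 (0.0986). The heat shock call ended with slide as a block (0.0698), with quantile scaling (0.0611) and without normoxia vehicle replicates 1 (0.079) or 2 (0.0548), normoxia ketamine replicate 4 (0.236), hypoxia vehicle replicates 1 (0.103) or 4 (0.191) or hypoxia ketamine replicates 2 (0.13) or 4 (0.0687).

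Of the single genes, NFKBIA (-1.74 ± 0.74), TLR4 (-1.46 ± 0.64), TGFB3 (-0.99 ± 0.40) and CYP4F21 (-1.81 ± 0.73) had negative interactions, and each call was lost without 1 of several arrays (values then -1.73 to -1.29, -1.41 to -0.99, -0.90 to -0.68 and -1.74 to -1.57). TLR4 (-0.82) and CYP4F21 (-0.38) did not pass with normexp. SNAI2 (1.2 ± 0.42), COPS7B (1.19 ± 0.33) and CHRD (0.93 ± 0.32) had positive ones that held with each array left out, although COPS7B (0.68) and CHRD (0.67) did not pass with normexp. SIRT4 (1.41), TNFRSF11B (1.29), GRIA4 (0.91) and CDKN1B (0.78) passed, but not with every array left out (values then 0.72 to 1.32, 0.92 to 1.32, 0.72 to 0.89 and 0.61 to 0.68), and SIRT4 (0.80), TNFRSF11B (0.83) and GRIA4 (0.64) did not with normexp. The SIRT4 interaction was 0.35 within slide 1 and 3.17 within slide 2, where normoxia vehicle replicate 3 was the only array of its group. Its change after hypoxia in vehicle fetuses (-0.31 and -2.965) and with ketamine in normoxic fetuses (-0.37 and -2.67) also lay mostly on slide 2. All of these SIRT4 values use that array. For AQP5 (1.06, with normoxia ketamine replicate 4 not well above background, and not called at 0.87 without normoxia vehicle replicate 2 or at 0.66 with normexp) and SLC9A3 (-0.997) only 1 of 2 probes went the way given, and with normexp SLC9A3 and TGFB3 turned to 0.28 and 0.38. In all, 265 probes had a positive and 142 a negative interaction, 407 where chance gives 646, and 0 passed after adjustment in limma.

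With slide as a block 426 probes had an interaction, within slide 1 229 and within slide 2 429. The median of all probes moved from 0.03 to 0.18 with normexp. The count was 247 without normoxia vehicle replicate 2, 674 without hypoxia vehicle replicate 2, 674 without hypoxia vehicle replicate 3, 987 without hypoxia ketamine replicate 2 and 239 without hypoxia ketamine replicate 3. It was 941 without the 2 arrays that stood apart and 713 without the 3 arrays with placental lactogen. Of the named genes GRIA4 (0.74) and CYP4F21 (-1.69) were not called without these 2, and without the 3 SIRT4 (1.42), TNFRSF11B (1.21) and CDKN1B (0.72). The replicate block ended the calls of GRIA4 (0.91), NFKBIA (-1.63), TLR4 (-1.31) and TGFB3 (-0.93), quantile scaling that of TNFRSF11B (1.27), and the deposited values those of SIRT4 (0.46), TNFRSF11B (0.71) and AQP5 (0.33).

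Over the 5 comparisons, the 22 calls of a list came from 11 lists, and each went the same way on both slides, as did 124 of the 131 values of named genes. These lists and genes were called or picked on the same arrays, so the agreement in sign is no independent support. Sizes could differ widely between slides 1 and 2, as for IGFBP1 after hypoxia in vehicle fetuses (1.45 and 6.68) and CATHL3 in ketamine fetuses (5.77 and 0.58). Within slide 2 alone 2, 0, 2, 0 and 1 lists were called in the 5 comparisons. No comparison called any of the other 14 tested lists, which were T and NK cells, complement and coagulation, leukocyte adhesion, oxidative stress, glucocorticoid response, apoptosis, proximal tubule, distal nephron, endothelium, vasoactive genes, ribosomal proteins, lipid metabolism, glutamate receptors and xenobiotic metabolism.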

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

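The test of fewer monocytes and macrophages and the final form of the slide test of the placental transcripts were chosen only after the results were seen, as were the analyses without the arrays that stood apart or carried placental lactogen.

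In the test of whether the response to hypoxia differed between vehicle and ketamine fetuses, the interaction in limma, 4 gene lists passed, but chance was not excluded, as given below. These were cytokines and chemokines (adjusted p = 0.0168), hypoxia-inducible targets (0.0223), heat shock genes (0.0406) and immediate early genes (0.00303). With a correlation estimated from the data 0 of the 4 passed, adjusted or unadjusted (adjusted p = 0.676 for each), and the same held with fry. With single arrays left out the adjusted p ranged from 0.00137 to 0.181, from 0.00458 to 0.103, from 0.00168 to 0.236 and from 5.07e-05 to 0.049, in the same order, and 3, 5, 7 and 0 of the 15 arrays ended the calls. Without the 2 arrays that stood apart, the cytokine (0.12), heat shock (0.305) and immediate early (0.154) calls also ended.

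Cytokine and immediate early genes were lower in hypoxic ketamine than in hypoxic vehicle fetuses, by a mean log2 difference of -1.40 over the 19 measured members. Each slide held as many hypoxic vehicle as hypoxic ketamine arrays, so an offset between the slides cancelled from this difference whatever the values. The difference was -1.48 on slide 1 and -1.32 on slide 2, so it did not rest on 1 slide. Nor did 1 fetus account for all of it, with -0.92 without hypoxia vehicle replicate 4, nearest to 0, and -1.83 without hypoxia vehicle replicate 3. Leaving out 1 array cannot show whether 2 fetuses carried it. The immediate early scores given above were high only in hypoxia vehicle replicates 1 and 4, while replicates 2 and 3 lay within the range of the hypoxic ketamine fetuses. The 8 monocyte and macrophage markers differed by a mean of -0.09 (SE 0.19 over the markers), which the rule chosen counted against fewer of these cells. That SE treats the markers as independent and holds no spread between fetuses, so the test cannot decide whether fewer of these cells contributed. Whether ketamine lowered the response stays open, since chance was not excluded: 8 of 35 splits of the hypoxic arrays called as many lists (real 5, highest other 6).

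Probe values varied more between hypoxic than between normoxic fetuses, with a ratio of the median probe SD of 1.39. Weak signal would lower that ratio in bright probes, and it was 1.40 in the brightest of 4 equal groups of probes and 1.31 in the dimmest. Slide would lower it between arrays of 1 group on 1 slide, and it was 1.37. Whether the fetuses differed in their response or in the depth of hypoxia was not tested. On the first principal component (31.2% of the variance), hypoxia vehicle replicate 4 (71.8) and hypoxia ketamine replicate 2 (51.9) lay farthest from the normoxic arrays (-28.3 to -21.8).

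Pregnancy-associated glycoprotein probes were higher in normoxic ketamine than in normoxic vehicle fetuses, by a mean of 1.91 over 9 probes, of which 8 were higher, PAG5 was lower (-0.84), and 6 were well above background on only 3 or 4 of the 15 arrays. Placental tissue in some samples is a candidate explanation, since placental lactogen was well above background only in normoxia ketamine replicates 1 (-2.97) and 2 (-3.30) and hypoxia ketamine replicate 2 (-6.18), against -9.20 to -7.90 on the other 12 arrays. The test chosen for it, the median difference of the 3 other trophoblast probes, gave 0.86, but that is the TKDP5 probe, which was as high in hypoxic vehicle (-6.61) as in normoxic ketamine fetuses (-6.62), differed by 0.52 within slide 1 and so did not follow these arrays, while PRP2 differed by 0.60, and by 1.71 within slide 1. The glycoprotein difference was 3.86 within slide 1 and 0.04 within slide 2; the first criterion for slide as the cause, a difference below 0.5 on at least 1 slide, was met, and it was replaced because arrays of 1 slide cannot differ through the slide. Expression by the kidney itself was not tested.

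Among groups of 4 arrays, 16 of 294 held 1 array far from the other 3, where chance gives about 1 in 20 (15), and 7 of the 16 were hypoxia ketamine replicate 2. In that array these were RTP4 (5.47, others 2.14 to 2.47), CYP4F21 (-5.07, others -5.58 to -5.52), MYD88 (-3.18, others -3.74 to -3.67) and TNFRSF11B (-5.49, others -4.55 to -4.39). Its list scores stood apart for cytokines (1.5, others -0.23 to -0.11), matrix genes (-0.29, others -0.10 to -0.07) and interferon-stimulated genes (3.58, others -0.54 to -0.25). In normoxic ketamine fetuses SELP (-4.69, others -5.54 to -5.50) and AQP5 (-7.09, others -5.82 to -5.56) stood apart in replicate 4, IGF1 (-2.94, others -3.42 to -3.39) in replicate 1 and NTN4 (2.34, others 1.97 to 2.01) in replicate 2. In replicate 3 these were AGTR1 (1.63, others 1.90 to 1.94), PDIA5 (1.13, others 0.61 to 0.67) and SLC9A3 (-6.19, others -5.81 to -5.76). In hypoxic vehicle fetuses CLOCK stood apart in replicate 1 (-4.35, others -4.83 to -4.76) and the toll-like receptor score in replicate 4 (0.83, others 0.26 to 0.33).

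Other splits of the same arrays into groups of the same sizes were counted. For hypoxia against normoxia in vehicle fetuses, 2 of 35 splits gave as many probes (real 2087, highest other 2359), so chance was not excluded, and 1 of 35 as many lists (real 7, highest other 6), so chance was excluded. That is the smallest share 35 splits can give, and it was not corrected for the other tests of splits. Without hypoxia vehicle replicate 3, 4 lists were called, and 0 with an estimated correlation (1 unadjusted) or with fry (7 unadjusted). Chance was therefore not firmly excluded for the lists either. For the same comparison in ketamine fetuses, 2 of 35 splits gave as many probes (real 1121, highest other 1274) and 4 of 35 as many lists (real 5, highest other 5), so chance was not excluded. For ketamine against vehicle in hypoxic fetuses, 19 of 35 splits gave as many probes (real 785, highest other 2699), so chance was not excluded. The highest, several times the real count, set hypoxia vehicle replicates 1, 3 and 4 and hypoxia ketamine replicate 2 against the rest and points to a structure of the samples. These 4 were the hypoxic arrays farthest from the normoxic ones on the first principal component (21.96 to 71.8). The other hypoxic arrays lay between -13.71 and 13.75. The split by slide gave 1135, and with slide as a block the real count was 772. For ketamine against vehicle in normoxic fetuses, 17 of 35 splits gave as many probes (real 350, highest other 643) and 23 of 35 as many lists (real 1, highest other 3), so chance was not excluded. Splits with 1 group on 1 slide gave 398 to 557, and the real count with slide as a block was 406. For the interaction, 62 of 100 splits gave as many probes (real 407, highest other 1691, several times the real count, which points to a structure of the samples) and 26 of 100 as many lists (real 4, highest other 7), so chance was not excluded. For the correlation between the responses to hypoxia, 3 of 70 regroupings gave as high a value (real 0.606, highest other 0.62). The real grouping thus did not give the highest value, and the share was not corrected for the other tests of splits. Without hypoxia ketamine replicate 2 the correlation was 0.393. Chance was therefore not firmly excluded for the correlation.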

How the results depend on the processing

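The analyses without the arrays that stood apart and without those with placental lactogen were chosen only after the data were seen, and the others were planned. Except where a reason is given, the cause was not tested.

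With camera at an estimated correlation and with fry, 0 lists were called in limma in each of the 5 comparisons, against 7, 5, 5, 1 and 4. Unadjusted, 1, 1, 2, 0 and 0 of these lists passed with the estimated correlation and 7, 1, 3, 0 and 0 with fry (2087, 1121, 785, 350 and 407 probes passed unadjusted). With normexp, 1256 probes passed unadjusted and 0 adjusted in hypoxia against normoxia in vehicle fetuses, 399 unadjusted in ketamine against vehicle in hypoxic and 113 in normoxic fetuses, and 198 in the interaction. In ketamine fetuses 3 lists were called for hypoxia, and the correlation of the responses was 0.543. Normexp turned CLOCK after hypoxia in ketamine fetuses to 0.075, CFTR after ketamine in normoxic fetuses to -0.13 and the interactions of SLC9A3 and TGFB3 to 0.28 and 0.38. Of 131 values of named genes, normexp left 84 on their side of the threshold, quantile normalization 125 and the slide block 127. Of the list calls, 5 ended with array weights, 3 with the replicate block, 2 with the mean over a gene's probes and 1 from the deposited values. Without the 2 arrays that stood apart 8 ended, and without the 3 arrays with placental lactogen 8.

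Without the filter, 1 probe passed the adjusted threshold for ketamine in normoxic fetuses, and the correlation was 0.542. With probes well above background on all 15 arrays, 1 passed for hypoxia in vehicle fetuses. Signal over background limits what can be said of genes such as IL6 and CFTR, which were not well above background on any normoxic vehicle array, so that their folds against that group are lower bounds. With slide as a block 4 probes passed the adjusted threshold for hypoxia in vehicle fetuses, and VEGFA turned to -0.032. With the replicate block (a paired form, though arrays with the same number were only weakly correlated, mean r 0.033 from -0.292 to 0.371 against -0.0105 for other numbers, and 7 of 15 arrays correlated best with their own number), 0 probes passed the adjusted threshold for hypoxia in vehicle fetuses (1820 unadjusted in limma) and 2 interaction lists were called. The replicate numbers were those of the scanner files, so this block cannot show whether the fetuses were paired. From the deposited values 0 probes passed for hypoxia in vehicle fetuses (2117 unadjusted in limma), VEGFA was -0.009, and 2 lists were called for ketamine in normoxic fetuses.

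With array weights, 16 probes passed the adjusted threshold for hypoxia in vehicle fetuses, 1819 unadjusted and 54 adjusted for hypoxia in ketamine fetuses, 1101 unadjusted for ketamine in normoxic fetuses with 2 lists, and 930 for the interaction, and TLR2 after hypoxia in ketamine fetuses was -0.044. With only the compared groups, 7 and 4 probes passed adjusted for hypoxia in vehicle and ketamine fetuses, 431 unadjusted for ketamine in hypoxic fetuses, and 671 unadjusted, 1 adjusted and 3 lists for ketamine in normoxic fetuses. Among only the probes with an unadjusted change at 0.01 after hypoxia in vehicle fetuses, the reversed share was 25.4% and the correlation 0.8945, which is over probes selected for their change and cannot be set beside the value across all probes.

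Without the 2 arrays that stood apart, 30, 2 and 3 probes passed adjusted for hypoxia in vehicle fetuses, hypoxia in ketamine fetuses and ketamine in hypoxic fetuses, with 1248 unadjusted for the last, 556 for ketamine in normoxic fetuses and 941 for the interaction. Then 3, 3 and 2 lists were called for hypoxia in ketamine fetuses, ketamine in normoxic fetuses and the interaction, the reversed share was 27.2%, the correlation 0.3705, CD14 -0.017 and TLR2 -0.20 after hypoxia in ketamine fetuses. Without the 3 arrays with placental lactogen, 16 probes passed adjusted for hypoxia in vehicle fetuses, 1460 unadjusted and 1 adjusted for ketamine in hypoxic fetuses, 1 adjusted for ketamine in normoxic fetuses and 713 unadjusted for the interaction. There was 1 list for hypoxia in ketamine fetuses, the reversed share was 30.2%, the correlation 0.3765, and TLR2 -0.32.

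Leaving out 1 array at a time, unadjusted counts ranged from 1304 (normoxia vehicle replicate 2) to 2454 (hypoxia vehicle replicate 2) for hypoxia in vehicle fetuses, from 832 to 1342 in ketamine fetuses, from 487 (hypoxia ketamine replicate 4) to 1606 (hypoxia ketamine replicate 2) for ketamine in hypoxic fetuses, from 211 (normoxia vehicle replicate 2) to 540 (normoxia vehicle replicate 3) in normoxic fetuses and from 239 (hypoxia ketamine replicate 3) to 987 (hypoxia ketamine replicate 2) for the interaction. Counts also moved without hypoxia vehicle replicate 2 for ketamine in hypoxic fetuses (1552), and for the interaction without normoxia vehicle replicate 2 (247) or hypoxia vehicle replicates 2 or 3 (674 each). Adjusted counts ranged from 0 to 55, 0 to 2, 0 to 3, 0 to 0 and 0 to 1, the highest of the first 3 without hypoxia ketamine replicate 2. Lists called ranged from 4 to 7, 3 to 7, 4 to 6, 0 to 3 and 2 to 5. The lowest were without hypoxia vehicle replicate 3, hypoxia ketamine replicate 2, hypoxia vehicle replicate 4, normoxia vehicle replicates 1 or 3, and normoxia vehicle replicate 3, normoxia ketamine replicate 4 or hypoxia ketamine replicate 4. For ketamine in normoxic fetuses 2 were called without normoxia ketamine replicate 1 and 3 without hypoxia vehicle replicate 4. The reversed share ranged from 7.99% (hypoxia ketamine replicate 3) to 34.3% (hypoxia vehicle replicate 2), with 10.0% without hypoxia ketamine replicate 4, 26.0% without hypoxia vehicle replicate 3 and 31.9% without hypoxia ketamine replicate 2. The correlation ranged from 0.393 (hypoxia ketamine replicate 2) to 0.666, with 0.528 without hypoxia vehicle replicate 3. VEGFA after hypoxia in vehicle fetuses turned to -0.22 without hypoxia vehicle replicate 1 and -0.12 without replicate 3, against a highest value of 0.302. Without hypoxia ketamine replicate 2, CD14 was -0.017 and TLR2 -0.20 after hypoxia in ketamine fetuses, against highest values of 0.507 and 0.676.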

Other observations

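In the 9 lists with too few measured genes to test, few members passed the unadjusted threshold. Of 4 cytokine and chemokine receptor genes, IL1RN was higher after hypoxia in vehicle fetuses (3.68) and lower with ketamine in hypoxic fetuses (-2.58). IL13RA1 was lower after hypoxia in ketamine fetuses (-0.68), lower with ketamine in hypoxic fetuses (-0.87) and negative in the interaction (-0.81). Of 4 MHC class II and antigen presentation genes, PSMB8 was higher after hypoxia in vehicle fetuses (1.82). Of 4 podocyte genes, VEGFA was lower with ketamine in hypoxic fetuses (-0.68). No member passed among B cell (1 gene), acute-phase (4), nephron progenitor (2), erythroid (3) or oxidative phosphorylation (3) genes, and 0 sex-linked genes were measured. IL1RN with ketamine in hypoxic fetuses, PSMB8 and the interaction of IL13RA1 were chosen after their values were seen.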
